A study of Drosophila melanogaster with 2 samples.

How the data were processed

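Chromatin immunoprecipitation followed by sequencing was done on whole Drosophila melanogaster larvae of mixed sex, collected at the wandering stage that ends larval life. The animals carried Brinker, a transcriptional repressor of genes regulated by the BMP ligand Dpp, fused to enhanced green fluorescent protein, and the precipitation used an antibody against the fluorescent protein, per the labels. Chromatin was sheared by sonication. The series has 1 group with 2 replicates, which the labels number 3 and 4 and call biological replicates. No second genotype, stage or mock precipitation was used here, so every comparison is between the replicates, between peaks and genomic background, or between genome builds.

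Peak lists in the narrowPeak layout were used, 8 in all, and they carry no header lines. For each of 2 genome builds, dm6 and dm3, there was a list of peaks and background for each replicate, a list called on the pooled alignments of both replicates, and a list of peaks retained by the irreproducible discovery rate (IDR) procedure, which keeps peaks ranked similarly in the replicates. These roles, the builds and the use of a control alignment come from the deposited sample notes. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The signal of a peak is the deposited value in the signal column; its scale is not stated. It was used to rank and describe peaks within a list, and ratios of it between replicates, between the pooled and replicate lists and between builds assume that the lists share a scale, which was not tested. The deposited −log10 q-value reached a ceiling of 3.43 in the dm6 IDR list, shared by 1351 peaks, so it was not used for ranking. The summit is the deposited offset from the start of the peak, and in 97.9% of the dm6 pooled peaks it equals the midpoint of the interval, so its precision may be limited. Sequencing depth is unknown from peak lists, and no interval in the text covers it.

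The dm6 lists hold 29999 peaks for each replicate and for the pool, and the dm3 lists 30000, so their lengths are fixed and carry no information. The dm6 IDR list holds 3413 peaks. Of these, 3412 are identical to entries of the pooled list and all 3412 are among its strongest. The IDR list is therefore built from both replicates, and the share of it found in a replicate is not an independent test. Median peak width was 416 bp in the dm6 IDR list.

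Positions were compared with the Release 6 genome sequence and the Ensembl release 115 annotation (BDGP 6.54), whose chromosome lengths contain every dm6 peak. Annotated transposable elements were left out of the genes. No dm3 sequence or annotation was used, so dm3 lists entered only counts and overlaps, and the density of dm3 peaks per arm, an alternative fixed beforehand, was not run. Genomic tests used the 6 arms 2L, 2R, 3L, 3R, 4 and X, which hold 3380 IDR peaks. Coordinates are given counting from 1 on dm6.

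Overlap between lists needed at least 1 bp, and chance overlap came from 100 circular shifts of the replicate list, or 20 where the replicates were compared directly. Shares carry 95% Wilson intervals, which cover counting error only. Spearman and Pearson correlations were computed across peaks, which are not independent replicates, with 1000 bootstrap draws for the interval. A promoter summit lies within 500 bp of any transcription start site (TSS). Promoter and other annotation shares were compared with 1000 random placements within the same arm by a two-sided permutation test with Benjamini-Hochberg adjustment over the 7 annotation classes, where the smallest p is 0.002. Density on X and on the 4 large autosome arms was compared by a two-sided exact binomial test on sequenced length. A gene was counted as having a peak when a summit lay in the gene or within 5 kb of it. Counts for 24 gene lists were compared with 10000 random lists of the 13945 protein-coding genes matched in 20 bins of gene length, two-sided, with Benjamini-Hochberg adjustment over the lists, where the smallest p is 0.0002. Of the gene names in the lists, 8 were not matched and are not analysed here, and 8 were matched through synonyms.

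For 21 sequence motifs, presence within 100 bp of the summit was compared with a window centred 1000 bp away on a random side, by the exact McNemar test with Benjamini-Hochberg adjustment over the motifs. Canonical 6-mers, of which there are 2080, were ranked by the log2 ratio of summit to flank windows. The relation of motif presence to signal was tested by 100000 permutations. Shuffled windows kept their dinucleotide counts, with 10 shuffles per window.

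Named genes follow a rule fixed, with the gene lists, motifs, tests and most alternatives, before the data were examined: the genes with the TSS nearest to the 25 strongest peaks, every member of the Brinker target and Dpp pathway lists, and of each other list the 3 members with the strongest peak. All 25 strongest dm6 IDR peaks lie on the mitochondrial genome, so the 25 strongest nuclear peaks are described in their place, a choice made after seeing the data.

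The tests were checked on simulated data. Of 200 random lists of 25 genes drawn from the 13945, 2.50% passed an unadjusted p of 0.05, and of 100 lists in which peaks were added to 40% of members, 83.0% passed. Of 200 sets of 3380 windows with no motif added, 3.00% passed, and of 20 sets with the motif added to 5% of windows, 95.0% passed. Both windows in these sets were flank windows, so the check does not cover the difference in GC content between summits and flanks. Overlap counts were checked against bedtools 2.31.1. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.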

Results

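Binding of Brinker was mapped in 2 replicates of whole larvae expressing the green fluorescent fusion protein. On dm6, 3413 peaks passed the IDR procedure, 3380 of them on the 6 chromosome arms and 33 on the mitochondrial genome. The mitochondrial entries lie in 10 distinct intervals and include all 25 strongest peaks. The strongest had a deposited signal of 17667, 9.88 times the 1788 of the strongest nuclear peak, and 27 of the 33 exceeded every nuclear peak. The files give no read counts, so the depth of each replicate is unknown. Everything described below for genes and sequence concerns the nuclear peaks.

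The strongest nuclear peak, with a signal of 1788, spanned positions 6612335 to 6612897 of 2L in an intron of CG11050. The next were at the promoter of CG14100 on 3L (signal 1166), in an intron of ush near the start of cbt on 2L (1142) and in an intron of the kinase gene Lk6 on 3R (1124). Signals above 1000 were also deposited at the promoters of CG18549, of gish, a casein kinase gene, and of CG11309. This last peak, at 21304380 to 21304741 of 3L, lies within 5 kb of Pc, the Polycomb gene. Of the 25 strongest nuclear peaks, 18 had the summit in a promoter, 4 in an intron, 2 between genes and 1 in a noncoding exon. The promoters included those of Gapdh2, a glycolytic enzyme gene (881), of mRpL41 (776), of shn (747), of Fkbp14 (746), of SLC5A11 (729), of the tyrosine kinase gene Btk (721) and of Chro, which encodes a chromosomal protein (701). The intergenic peaks were 11917 bp from the nearest TSS, that of CG13323, and 3773 bp from that of CG31668. In both replicates 24 of these 25 peaks ranked among the strongest 100. The exception, the promoter of GstE13 on 2R (678), ranked 57 in replicate 3 and overlapped no entry of replicate 4.

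The first comparison asked how far the replicates list the same sites. Among genes of the Dpp pathway, the strongest peak of shn had a signal of 415 in replicate 3 and 334 in replicate 4, that of Dad 211 and 184, and that of tkv, which encodes a Dpp receptor, 152 and 145. The values differed more at CtBP, a corepressor gene (90.6 and 30.1), at dpp itself (39.6 and 78.2) and at cv (126 and 59.9). At the weak peaks of put and myo they were 54.4 and 44.3, and 47.9 and 43.2. At the peak near phol the values were 297 and 15.8, the second from a neighbouring entry that only touches the peak, and the promoter peak of elav, a neuronal gene, had 182 in replicate 3 and no entry in replicate 4. Of the 3413 IDR peaks, 2702 overlapped one of the 3413 strongest peaks of replicate 3 (79.2%, 95% interval 77.8 to 80.5) and 2817 one of replicate 4 (82.5%, 81.2 to 83.8), against 2.80% and 2.74% after circular shifts. Compared directly, 2252 of the 3413 strongest peaks of replicate 3 (66.0%, 64.4 to 67.6) overlapped one in replicate 4, with 2.59% by shifts. Across the 3276 IDR peaks with an entry in both, Spearman's rho was 0.627 (95% bootstrap interval 0.602 to 0.651) and Pearson's r of log2 signal 0.839, or 0.712 without the mitochondrial genome. IDR peaks are nearly all among the strongest of the pooled list. At nuclear peaks with both entries, pooled signal was a median of 0.992 times the sum of the replicate signals. Both correlations and the interval therefore describe a range selected on that sum, and not the full lists. The median log2 ratio of replicate 3 to replicate 4 was 0.03 and its SD 0.55. Among nuclear peaks divided by signal into 5 groups, this SD was 0.63 in the weakest (649 peaks) and 0.41 in the strongest (649 peaks), with no test of the difference. Of the nuclear IDR peaks, 134 had no overlapping entry in replicate 4 and 2 had none in replicate 3. With a replicate summit required within 100 bp, these counts were 290 and 162. At the 134, the pooled signal was a median of 1.83 times that of replicate 3, against 1.94 times where both replicates had an entry, so a missing entry does not show that signal was missing, as far as the lists share a scale.

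**Figure D1:**
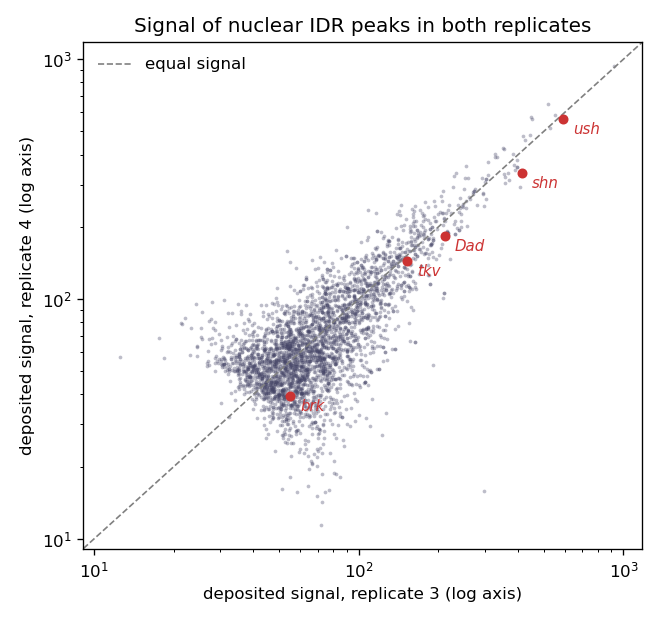
Deposited signal of each nuclear IDR peak in replicate 3 (x axis, log scale) and replicate 4 (y axis, log scale), for the 3244 peaks with an overlapping entry in both. Red points are the strongest peaks of 5 named genes, and the dashed line marks equal signal. Strong peaks such as those at ush and shn lie near the line, and weaker ones scatter around it, with rho of 0.617 over the nuclear peaks.

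The second comparison asked where in the genome the nuclear peaks lie. Promoters held 1505 of 3380 summits (44.5%, 42.9 to 46.2), 3.28 times the 13.6% of random placements (two-sided permutation p = 0.002, the smallest possible). Examples are the promoters of numb, a regulator of Notch signalling (414), of fkh, a salivary gland transcription factor gene (484), of bowl (445), of ph-p, a Polycomb group gene (665), of Dll, a limb gene (269), and of RpL7, a ribosomal protein gene (235). Promoters took precedence over the other classes, so their larger share of summits lowers the shares left for the rest. Shares among summits outside promoters alone were not tested. Introns held 1305 summits (38.6%), close to the 39.2% of random placements (permutation p = 0.515, adjusted p = 0.515), among them the strongest summits of Eip75B (516), Diap1, a cell death inhibitor gene (574), Egfr (272) and Antp (222). Intergenic sequence held 468 (13.8% against 27.5%) and 3' UTRs 38 (1.12% against 4.36%), both fewer than at random (permutation p = 0.002, the smallest possible, adjusted p = 0.0035 over the 7 annotation classes). Random placements left out only unsequenced gaps, so they also fall in annotated transposable elements. These make up 5.93% of the arms and hold 4 IDR summits (0.118%), and their effect on the random shares was not tested. Coding exons outside promoters held 2 summits (0.0592%) where random placements gave 13.9% (permutation p = 0.002, adjusted p = 0.0035). Among the 676 weakest peaks the promoter share was 37.9%, and among the 676 strongest 51.3%. It was 50.9% (49.2 to 52.5) among the strongest peaks of replicate 3 and 42.6% (41.0 to 44.3) among those of replicate 4.

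**Figure D2:**
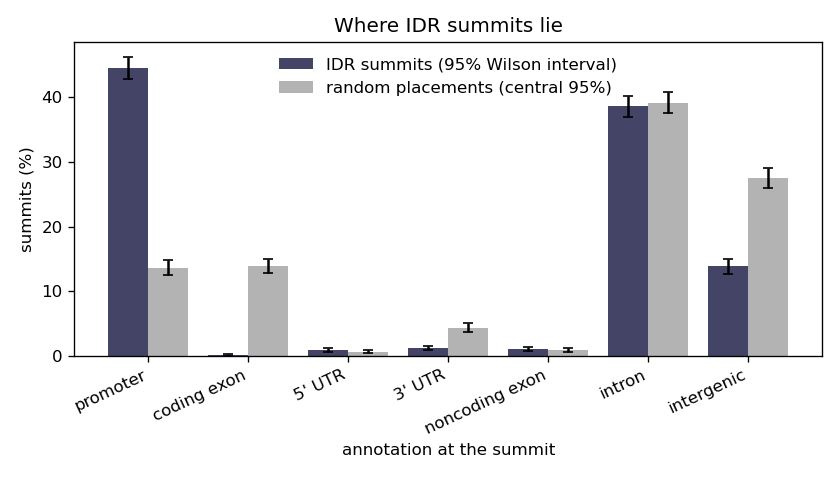
Percent of the 3380 nuclear IDR summits (dark bars, 95% Wilson intervals) and of random placements in the same arms (grey bars, central 95% of 1000 draws) in each annotation class. Promoters hold 44.5% of summits against 13.6% at random, and coding exons outside promoters 0.0592% against 13.9%.

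Peak density differed between the arms. It was highest on 3L, with 30.2 peaks per Mb, where Eip75B and Diap1 lie, and on 2L, with 29.2, where ush and tkv lie. It was 23.7 on 3R and 26.3 on the small arm 4, which holds peaks at ci and sv. The X chromosome, with peaks at bi, Myc and sog, had 20.1 per Mb, 0.760 times the 26.4 of the 4 large autosome arms (two-sided exact binomial p = 1.3e-08). The ratio was 0.801 in the strongest peaks of replicate 3 and 0.654 in those of replicate 4. The test assumes an equal dose of X and autosomes. Dose of X differs by sex and the larvae were of mixed sex, so the lower density cannot be read as less binding on X.

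The gene list comparison asked which groups of genes carry peaks more often than genes of similar length. Of the 13945 protein-coding genes, 3753 (26.9%) had a summit in the gene or within 5 kb. Among 31 Dpp pathway genes, 22 had a peak against 12.3 in matched lists (permutation p = 0.0006, adjusted p = 0.00288 over 24 lists). In the strongest peaks of replicate 3 or replicate 4 alone, 19 members had a peak, with adjusted permutation p of 0.149 and 0.0582, so neither replicate alone gave this call. shn, which encodes a zinc finger protein acting with Mad and Medea, had 13 peaks, the strongest in a promoter at 11173521 to 11173798 of 2R. Dad, an inhibitory Smad gene, had 8 peaks, with the strongest (398) in an intron at 17065063 to 17065287 of 3R. tkv had 8 (295 for the strongest) and the glypican genes dlp and dally 8 and 4 (190 and 171). wit had 3, of which the strongest (358) is shared with its neighbour Gad1. The corepressor gene gro had 2 (252), Med 2 (144), Mad 2 (94.3) and dpp 1 (116). The strongest peaks counted for Med, Mad, babo and myo lie at promoters nearest to other genes. These are CycG, toc, CG33199 and ey, with TSSs 111, 11, 206 and 60 bp away. Mad had 0 peaks among the strongest of replicate 4, dpp and myo 0 among those of replicate 3, and mav, with 1 IDR peak (88.0), 0 among those of either. The genes gbb, scw, sax, Smox, tsg, tld, tok, Smurf and daw had none.

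Of 26 protein-coding genes listed as Brinker or Dpp targets, 14 had a peak against 10.7 in matched lists, which was not past the threshold (permutation p = 0.242, adjusted p = 0.387). With each peak given to its nearest TSS, 16 members had a peak against 7.19 (adjusted permutation p = 0.0016), and without matching on length the 14 were above the 6.98 of Fisher's exact test (adjusted p = 0.00938). With summits within 1 kb of a TSS the direction turned, with 5 members against 5.90 (adjusted permutation p = 0.913). The target with the strongest peak was ush, with 11 peaks, the strongest 1367 bp from the TSS of cbt, and Dad, with 8 peaks, is also among these targets. magu, a secreted regulator of Dpp, had 5 peaks (187). al and Myc had 2 each (142 and 145). bi (184), sog (167), wg (149), nab (135), Doc1 (117), salm (104), brk itself (92.0), vn (90.3) and vg (84.1) had 1 peak each, as did mir-ban (166), a microRNA gene outside the test. The brk peak, at 7314214 to 7314629 of X, lay 6483 bp from the brk TSS and was not among the strongest of replicate 4, and the vg peak had no entry in replicate 4. The other targets, salr, tup, zen, pnr, Doc2, Doc3, Ance, lab, Ubx, tld, bap and rho, had no IDR peak, although tup had 1 peak among the strongest of each replicate and Ance 1 in replicate 3.

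**Figure D3:**
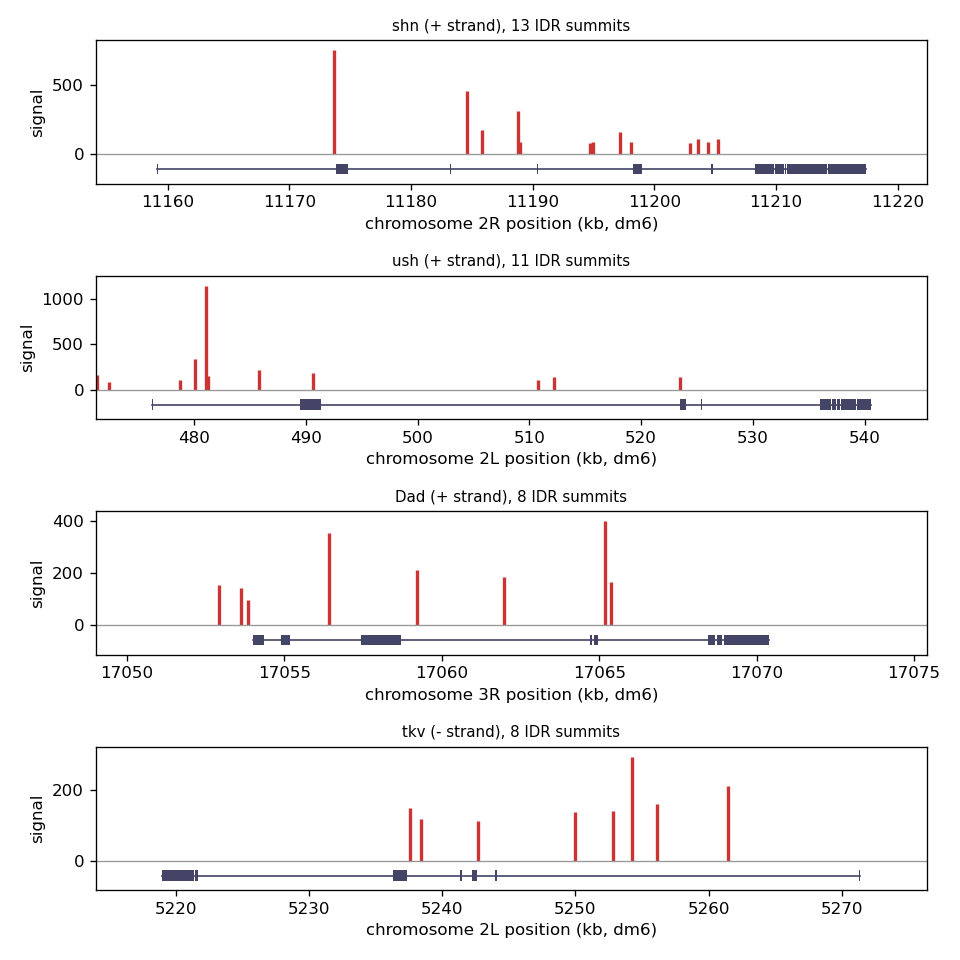
IDR summits (red lines, height in deposited signal) over shn, ush, Dad and tkv on dm6, each with 5 kb on either side; x axes are positions in kb and blue boxes are annotated exons of the gene. The loci hold 13, 11, 8 and 8 summits.

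Genes of the Notch pathway and of the ecdysone cascade held peaks more often than matched genes, as did ribosomal protein and heat shock genes. Of 24 Notch pathway genes, 19 had a peak against 7.19 (permutation p = 0.0002, the smallest possible, adjusted p = 0.0016), with the strongest at numb (414), the ubiquitin ligase gene neur (320) and E(spl)malpha-BFM (316). Neighbouring E(spl) genes share peaks. Of 25 genes of the ecdysone cascade, the hormone response that drives metamorphosis, 20 had a peak against 11.0 (permutation p = 0.0002, adjusted p = 0.0016), among them MsrA (537), Eip75B (516) and Eip78C (448). The 24 peaks of Eip75B were the most of any protein-coding gene. The MsrA peak lies 149 bp from a TSS of CG7841. With summits within 1 kb of a TSS, 12 ecdysone genes had a peak and the adjusted permutation p was 0.0501. Of 92 ribosomal protein genes, 33 had a peak against 19.0 (permutation p = 0.0004, adjusted p = 0.0024), among them RpL27 (326) and RpL7 (235), and the peak counted for RpL27 lies at the promoter of CG4743. Without matching on length the adjusted p of Fisher's exact test for the ribosomal list was 0.109. Of 18 heat shock genes, 10 had a peak against 3.73 (permutation p = 0.0028, adjusted p = 0.0112), and Hsp23, Hsp27 and Hsp67Ba share 1 promoter peak (610). Matched lists do not reproduce such sharing between neighbours, so the p of the heat shock and Notch lists may be too small. Of 111 histone genes, 0 had a peak against 17.2 (permutation p = 0.0002, adjusted p = 0.0016). Histone genes are near-identical repeated copies, so this count is uncertain. The matched lists treat members as independent genes, which repeated copies are not, so this p is not evidence that peaks avoid histone genes.

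**Figure D4:**
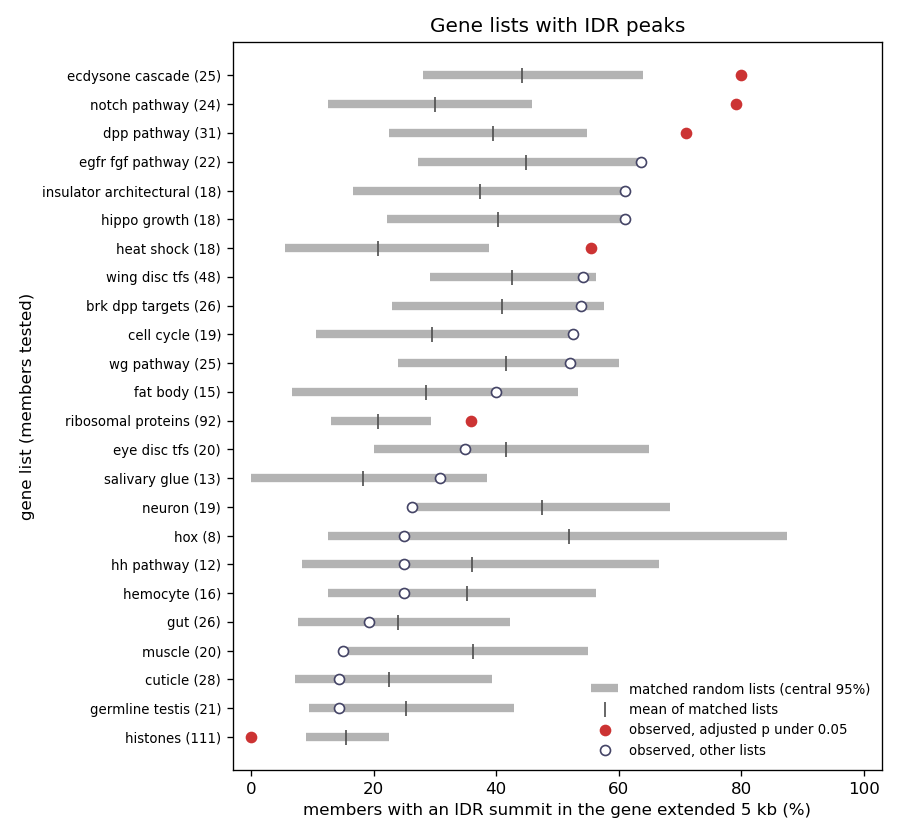
Percent of each gene list with an IDR summit in the gene or within 5 kb (points), against the central 95% of 10000 length-matched lists (grey bars) and their mean (ticks). Red points have an adjusted p under 0.05: 5 lists lie above their matched lists and the histone genes, at 0%, below. Matched lists do not reproduce repeated copies or neighbours that share a peak, as in the histone, heat shock and Notch lists.

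Of the 24 lists, 18 did not pass by the main test, the Brinker targets among them, and several passed by an alternative. Wing disc transcription factor genes had peaks at 26 of 48 members (20.4 in matched lists, permutation p = 0.13, adjusted p = 0.241), led by bowl (445), elB (351) and Dll (269). EGF and FGF pathway genes had 14 of 22 (9.89, permutation p = 0.105, adjusted p = 0.217), led by edl (356), Egfr (272) and aop (259). By nearest TSS, wing disc factors (25 against 13.7) and the EGF and FGF pathway (14 against 6.78) passed, both with an adjusted permutation p of 0.0042, and by Fisher's exact test without matching their adjusted p were 0.0003 and 0.00133. Hippo pathway genes had 11 of 18 (7.24, permutation p = 0.109, adjusted p = 0.217), led by Diap1 (574), ex (304) and ds (263). The Hippo list passed in replicate 4 alone (13, adjusted permutation p = 0.0329), within 1 kb of a TSS (10 against 4.06, 0.0221), by nearest TSS (11 against 4.89, 0.0115) and by Fisher's exact test (0.00712). Insulator and chromatin architecture genes had 11 of 18 (6.72, permutation p = 0.0632, adjusted p = 0.169), led by Pc, ph-p and phol, and cell cycle genes 10 of 19 (5.62, permutation p = 0.0536, adjusted p = 0.161), led by twe (226), E2f1 (222) and CycB (215). The insulator list passed by nearest TSS (9 against 4.23, adjusted permutation p = 0.0467) and by Fisher's exact test (0.00712). The cell cycle list passed in replicate 3 alone (14, adjusted permutation p = 0.00384), with peaks at or above the median signal (9 against 3.75, 0.0453) and by Fisher's exact test (0.0356). Wg pathway genes had 13 of 25 (10.4, permutation p = 0.372, adjusted p = 0.503), led by fz (335), fz2 (319) and nmo (219), and passed by Fisher's exact test (adjusted p = 0.0256). Eye disc factors had 7 of 20 (8.34, permutation p = 0.701, adjusted p = 0.732), Hox genes 2 of 8 (4.15, p = 0.238, adjusted p = 0.387) and Hedgehog pathway genes 3 of 12 (4.32, p = 0.624, adjusted p = 0.681), with the strongest at sv (224), Antp (222) and rdx (140). The strongest peaks counted for twe, nmo, Pc and phol lie at promoters nearest to other genes. These are EndoGI, HP4, CG11309 and CG3437. For the strongest peaks of elB, fz and sv, the nearest TSSs are those of ppk, CG13482 and Cals.

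Markers of the tissues that whole larvae contain gave counts within the range of matched genes. They were 3 of 20 for muscle (7.24, permutation p = 0.053, adjusted p = 0.161), 5 of 19 for neurons (9.04, p = 0.097, adjusted p = 0.217), 6 of 15 for fat body (4.27, p = 0.461, adjusted p = 0.553) and 4 of 13 for salivary gland and glue genes (2.38, p = 0.395, adjusted p = 0.503). They were 4 of 16 for blood cells (5.65, permutation p = 0.542, adjusted p = 0.62), 4 of 28 for cuticle (6.32, p = 0.399, adjusted p = 0.503), 5 of 26 for gut (6.24, p = 0.752, adjusted p = 0.752) and 3 of 21 for germline and testis genes (5.29, p = 0.346, adjusted p = 0.503). In the strongest peaks of replicate 4 alone, neuronal genes had 3 of 19 (adjusted permutation p = 0.0288). Several of the strongest marker peaks lie at promoters of other genes: those of Sgs1, a glue gene, and Jon25Biii, a gut protease gene, are 1 peak (400) at mRpL24, and that of Lsp2, a fat body storage protein gene, is at yps (213). The peak of fkh lies at its own promoter. That of Mef2, a muscle regulator (340), lies within the gene but in a 3' UTR, and the nearest TSS is that of Etf-QO, 4360 bp away.

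The sequence comparison asked whether the Brinker site, GGCGYY, is concentrated at summits. It was not higher there: 482 of 3380 summit windows held the motif (14.3%, 13.1 to 15.5) and 642 flank windows (19.0%, 17.7 to 20.4; exact McNemar p = 2.34e-07, adjusted p = 1.23e-06 over 21 motifs). The direction turned with the background: against flank windows of the same GC content the motif was at 17.7% in 2271 summit windows and 15.1% in flanks (Fisher's exact p = 0.0199). Summit windows had a mean GC content of 35.6% (SD 7.12 over windows) and flanks 41.4% (SD 9.05). The longer form TGGCGYY was at 6.63% and 8.08% (exact p = 0.0266, adjusted p = 0.0507), against 5.13% in shuffled summit windows. The GC-rich Mad site was at 18.3% and 29.5% (exact p = 3.27e-27, adjusted p = 6.87e-26), against 14.98% in shuffled summit windows. For both, the direction turned with the background as well. Of the 21 motifs, 4 were higher at summits: the DNA replication-related element TATCGATA (3.08% against 0.651%, exact p = 6.07e-14, adjusted p = 6.38e-13), GAGAG, the site of GAGA factor (28.3% against 23.6%, p = 6.36e-06, adjusted p = 2.23e-05), the GATA site (30.1% against 24.6%, p = 4.41e-07, adjusted p = 1.85e-06) and the M1BP site GGTCACACT (0.592% against 0.207%, p = 0.0192, adjusted p = 0.0402). The GATA site was in 30.9% of shuffled summit windows. In narrower windows, reaching 50 bp to each side, GAGAG was at 13.9% on the summit, 20.4% and 20.9% at 150 bp on either side, and 12.6% and 12.5% at 1000 bp, so its rise flanks the summit. The Smad box, the E-box, the Scalloped site and the ecdysone receptor site AGGTCA were lower at summits than in flanks, and the remaining 11 motifs did not pass. Against shuffled summit windows the E-box was more frequent (57.9% against 53.2%) and the Scalloped site was not lower (6.98% against 6.86%).

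**Figure D5:**
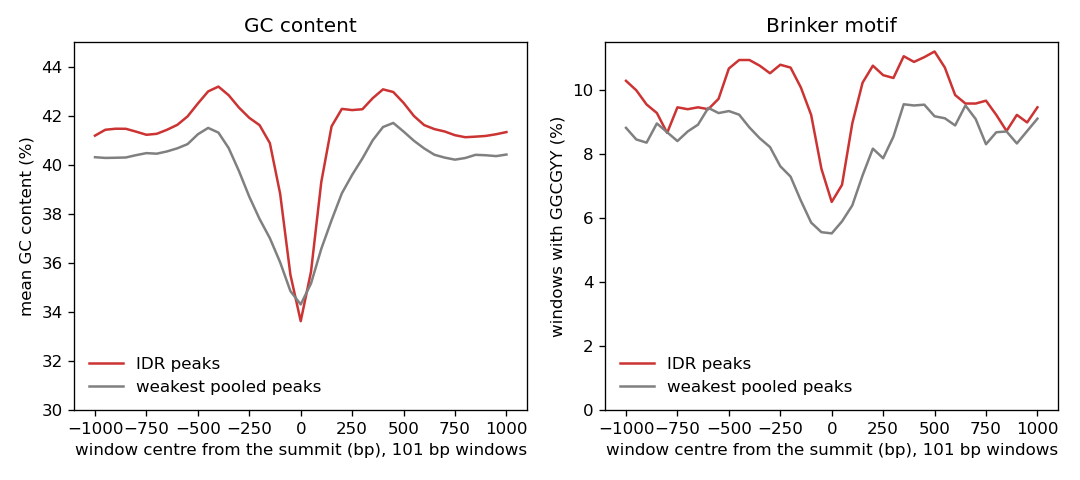
Mean GC content (left, %) and percent of windows reaching 50 bp to each side with GGCGYY (right), by distance of the window centre from the summit in bp, for the nuclear IDR peaks (red) and the 8000 weakest pooled peaks on the arms (grey). GC content at the summit is 33.6% for IDR peaks and 34.3% for the weakest peaks, and the motif share 6.51% and 5.53%.

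Among the 2080 canonical 6-mers, the highest ratio of summit to flank windows was that of ACACTG (480 against 258 windows, log2 ratio 0.89), followed by ACAGTG (503 against 272, 0.88). Of the 4 forms of the Brinker site, GGCGCC ranked highest at 967 (89 against 98 windows), followed by AGCGCC at 1244, AACGCC at 1451 and GACGCC at 1906. Against shuffled summit windows GGCGCC ranked 15, with 89 windows against 40. The other forms ranked lower there: AGCGCC 220 (177 against 132), GACGCC 756 (97 against 95) and AACGCC 1329 (160 against 187). A relation of GGCGYY to peak signal did not pass the test (Spearman's rho = -0.0229 across 3380 peaks, two-sided permutation p = 0.183). Within 50 bp of the summit it did, with rho = -0.0419 (permutation p = 0.0144).

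The last comparison set the 2 genome builds side by side. The dm3 IDR list holds 4134 peaks, 1.21 times the dm6 count. The arms held similar shares of the peaks in both: 22.5% in dm6 and 23.4% in dm3 on 3R, 20.3% in both on 2L, 17.2% and 17.3% on 2R, and 13.9% and 13.3% on X. On the mitochondrial genome dm3 listed 8 peaks where dm6 listed 33.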

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

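Peaks outside the chromosome arms are a signal in data that the comparisons of genes and sequence do not use. The tests of the mitochondrial peaks were chosen after the result was seen.

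On dm6, 33 IDR peaks lie on the mitochondrial genome, and on dm3 8. The dm3 list also holds 6 peaks on unplaced or heterochromatic sequences, which are not analysed further here.

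The mitochondrial peaks do not come from 1 library alone: each replicate lists 31 of them among its strongest 3413. They cover 84.4% of the 19524 bp molecule, whereas the most densely covered nuclear stretch of that length reaches 20.3%, so reads from mitochondrial DNA along the whole molecule are a candidate explanation. The strongest mitochondrial signal was 9.44 times higher on dm6 than on dm3 (17667 and 1872), while the strongest nuclear signals were 1788 and 1796, so the placement of mitochondrial reads on each build may also contribute. No biological explanation was tested, since the series has 1 group and no mock precipitation was used here.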

How the results depend on the processing

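Comparisons with summits placed within 100 bp, with GC-matched weakest peaks, outside ribosomal protein genes and without the mitochondrial genome were chosen after seeing the data. Promoter enrichment (2.37 to 3.74 times) and the lower density on X (0.654 to 0.801 times) kept their direction and side of the threshold under every alternative run. Density per arm on dm3 was not run, since no dm3 reference was used here. With single replicates, promoter enrichment was 3.13 to 3.74 times, 6 to 7 gene lists passed, and the best Brinker 6-mer ranked 698 to 1030. Of 117 named genes with an IDR peak, 107 had one among the strongest peaks of each replicate.

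Requiring a reciprocal overlap of 50% gave replicate shares of 68.6% (replicate 3) and 73.2% (replicate 4) and a rho of 0.484. Summits within 100 bp gave 72.8%, 76.3% and 0.597. Taking 2 times N replicate peaks gave 97.4% and 94.2%, the 1707 IDR peaks at or above the median signal 97.8% and 95.4%, and dm3 81.2% for replicate 3. The cause was not tested.

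The number of gene lists past the threshold, 6, became 11 with each peak given to its nearest TSS and 12 by Fisher's exact test without matching. Counts that changed side of their matched mean, without passing before or after, were those of the Hedgehog pathway (5 without replicate 4, 4 by nearest TSS), Brinker targets (5) and the Wg pathway (4) within 1 kb of a TSS, and eye disc factors (7) without matching. The cause was not tested.

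The summit minus flank difference for GGCGYY, -4.73 percentage points, was -2.16 within 200 bp (exact McNemar p = 0.0594). It reversed to 1.48 against 1 shuffle of the windows (exact McNemar p = 0.0697), 2.60 against GC-matched flanks (Fisher's exact p = 0.0199) and 2.47 against GC-matched weakest peaks (Fisher's exact p = 0.00289). These backgrounds hold base composition or GC content of the windows equal by construction. Permuted forms of the motif keep its letters and were counted in the same summit and flank windows. Over 59 such forms the mean difference was -5.70 points, so the deficit of GGCGYY was 0.969 points smaller (permutation p = 0.7). The best rank of a Brinker 6-mer was 15 against shuffled windows. The relation to signal was -0.0419 within 50 bp (permutation p = 0.0144), and the cause was not tested. Unknown depth leaves the precision of single peak signals open.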

Other observations

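Longer sequences stood out at the summits, and were chosen after seeing the data. CTCAGTGCA, ACTGAGAGA and GCACTGAGA were among the 9-mers with the highest summit to flank ratio on chromosome 2 alone, and on the other arms they were in 27, 40 and 32 of 2112 summit windows against 3, 4 and 2 flank windows (exact McNemar adjusted p = 1.69e-05, 1.54e-07 and 2.31e-07 over 10 k-mers). Of the 10 k-mers chosen in this way, 7 passed there and 3 did not: GTATTACA (15 against 11 windows, exact adjusted p = 0.619), TAAATCTTA (10 against 13, 0.678) and ATATCTAAA (18 against 10, 0.231). Of the 7, 5 share the core CTGAG and overlap one another, as does CACTGAGAG, so they are not separate observations. Over all arms CACTGAGAG was in 60 summit and 7 flank windows, and CACAGTGG in 120 and 30, while shuffled windows held these 2 k-mers 5.56% as often as the summit windows. In 0 of 154 windows did the 12 bp on both sides of either k-mer recur in another window.

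Genes with many peaks outside the fixed lists, named after their values were seen, included sbb with 19 peaks, kirre with 14 and bun with 13.

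The tests of the Brinker site between the strongest and weakest peaks and against the weakest pooled peaks, and the test of the weakest peaks in coding exons, were chosen after the result was seen. The shuffled windows and the peaks at or above the median signal were alternatives fixed beforehand, and their use to weigh explanations was chosen afterwards. The test of the site at Dpp genes, that of coding exons at matched GC content and that of the X share were written beforehand.

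The Brinker site was less frequent at summits than in flanks, at 14.3% and 19.0%. Without the peaks below the median signal the difference was -5.20 percentage points (13.7% and 18.9%, exact McNemar p = 7.35e-05). This cannot decide on dilution by weak peaks, since flanks have a higher GC content than summits (41.4% against 35.6%), which alone can leave a deficit. Base composition is a candidate explanation for the deficit: shuffled summit windows held the site at 13.3%. Binding through the site at genes of the Brinker target and Dpp pathway lists stays open, because 20 of 95 peaks there held it (21.1%, 14.1 to 30.3) and 14.1% of other peaks (two-sided Fisher's exact p = 0.0721), too few peaks to decide. Dilution by weak peaks, in whole or in part, also stays open: the 676 strongest peaks held the site at 11.2% and the 676 weakest at 14.1% (two-sided Fisher's exact p = 0.141), or 10.8% and 12.7% among 537 windows each at matched GC content (p = 0.394), while IDR peaks held it more often than the weakest pooled peaks (14.2% against 11.7% at matched GC content, p = 0.00289). That last contrast is not particular to the site: without GC matching, GAGAG was at 28.3% against 18.2% and TATCGATA at 3.08% against 0.625%. IDR and weakest pooled peaks also differ in promoter share (44.5% against 12.4%), so the contrast cannot decide on dilution.

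Summits almost never lay in coding exons outside promoters: 2 of 3380 IDR summits did, against 13.9% of random placements. Positions in promoters, 44.5% of summits and 13.6% of random placements, were not counted as coding. GC content alone is argued against as the whole cause, since random positions of the same GC content lay in coding exons at 4.73% (3.70 to 5.59 over 100 draws). The 8000 weakest pooled peaks were at 1.44% where random positions give 14.0%, although their promoter share was 12.4% against 13.5%. Avoidance of coding sequence outside promoters may therefore be a property of the listed entries in general, and no biological explanation was tested.

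The share of X among the strongest peaks on the large arms was 14.7% in replicate 3 and 12.4% in replicate 4 (two-sided Fisher's exact p = 0.00479), outside promoters 15.3% and 12.9% (p = 0.0477), within promoters 14.2% and 11.6% (p = 0.0325) and in the full lists 16.6% and 13.5% (p = 8.96e-26), with p not adjusted over these 4 comparisons. The test treats the lists as independent, although 66.0% of the 3413 strongest peaks of replicate 3 overlapped one of replicate 4. Each replicate is a single library, so these p do not measure a difference between replicates beyond the counting of peaks. Dose of X also differs by sex, and the larvae were of mixed sex.

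Of the 500 strongest nuclear IDR peaks, 10 had no overlapping entry in replicate 4 and 0 none in replicate 3, and with a summit required within 100 bp, an alternative chosen after seeing the data, 16 and 4.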
